A study of Arabidopsis thaliana with 124 samples.

How the data were processed

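ChIP-seq was done on whole Arabidopsis thaliana seedlings (Col-0) of lines that carry 1 of 21 transcription factors tagged with YPet by recombineering, per the labels' protocols. Seedlings were grown for 3 days in the dark and treated for 4 h with 10 µM ABA or ethanol. Chromatin was crosslinked with formaldehyde, sonicated and precipitated with a polyclonal antibody against GFP, and libraries were sequenced on an Illumina instrument. Untagged Col-0 chromatin precipitated with the same antibody was the control, per the series' design text. Both control libraries are labelled with 10 µM ABA, and whether they served the mock lists too is not given. Samples were grouped by factor and treatment from their titles. No values of the 2 Col-0 libraries by themselves were analysed here.

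The deposited data are 42 peak lists in narrowPeak form, 1 per factor and treatment. The submitters' processing notes name Bowtie 0.12.7, MACS2 2.0.10 and the build TAIR10, and which step each was used for is not given in the sources used here. Peak names and file names show that the authors pooled the replicates of a group into 1 list and kept a set they call optimal at a −log10 p of 16. The lowest −log10 p of a list was tested on the files, and 3 lists start more than 1 unit above 16. They are those of GBF3 under ABA (17.98, against 16 under mock) and of NFYB2 under ABA (19.25) and mock (17.58). For GBF3 and NFYB2 the ABA and mock lists are therefore compared at unlike cutoffs. The authors' fold enrichment of each peak, a ratio, and the authors' −log10 p of each peak, as deposited, were used only to describe, rank or filter peaks within a list. The position of the summit within each peak was used as deposited by the authors. The column for q-values holds -1 throughout, so peaks were ranked by −log10 p where q had been planned. The files hold no read counts, so depth is unknown and its effect on the length of a list cannot be computed. The series names these libraries as its control without saying which lists were made against them. A control of ABA-treated seedlings alone can change the number of peaks under ABA and under mock differently, and a shared control can add the same peaks to several lists. Unchanged groups could not be simulated from peak lists, so the number of shared regions expected from independent lists is given in place of that.

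Peaks were compared by overlap of at least 1 bp. Regions were made by merging the peaks of all lists, and a factor was counted in a region that any of its peaks touched. Coordinates are those of the peak lists, 1-based, on TAIR10. Gene names and gene neighbourhoods come from an NCBI gene table of assembly TAIR10.1, which holds no strand, so no transcription start site could be used as had been planned. In its place a summit was given to the nearest protein-coding gene (distance 0 inside a gene) within 2000 bp, and "near a gene" means outside genes and within 1000 bp of one. No gene coordinate from that table is printed. As a check that the table and the peaks share positions, summits were shifted along the chromosomes. The share of summits inside genes was 33.8% without a shift, 34.9% at 50 bp to either side and 37.5% and 37.4% at 100 bp, so its minimum lay at no shift. Of 299 gene list entries, 298 matched the table. No reference genome was used here, so the planned searches for family motifs were not run.

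Tests across factors were two-sided sign-flip permutation tests of the mean over factors (100000 resamples, exact for up to 16 units), with the 2 treatments of a factor as a pair. The within-family test permuted family labels, using log2 of observed over expected shared regions with 0.5 added to both. Co-binding and the number of genes with at least 10 factors were tested by swapping the treatments within factors. Each of 22 gene lists, fixed before the data were examined, was compared with 10000 random lists matched on 10 classes of the summed distance to both neighbouring genes (upstream length had been planned), with Benjamini-Hochberg adjustment over the lists. The smallest p this allows is 0.0002. The exact sign test per gene was added after the data were seen. These p-values measure the spread between factors or genes, not between replicate libraries, and the labels do not say whether replicates came from separate cultures. Intervals of shares of peaks are 95% Wilson intervals and cover counting error only. Genes of the same list, and factors bound at the same regions, are not independent of each other.

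The genes named were set by a rule: the 10 genes with the largest net gain in factors and the 10 with the most negative one (ties by the higher number in the treatment of the direction, then by gene code), the 5 genes with the most factors under ABA, up to 4 members of a list with the most factors (not given for every list) and any member with a net change of at least 5, the gene at the strongest ABA peak of each factor, 22 known factor and target pairs, and the 21 factors. Members at a tie or with fewer factors under ABA that are named beyond it were chosen after their values were seen.

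Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated lists. A mean log2 change in peak number of 0.69 and a kept share difference of 30.8 points came back as put in. For the comparison of gene lists, run on 27432 genes, 200 genes were given up to 8 extra factors each and had a mean gain of 7.14 against 1.36 elsewhere. A list of 20 of these genes passed the test (adjusted p = 0.0082 in a permutation test), and of 40 lists of other genes none did after adjustment and 3 had an unadjusted p below 0.05. Alternatives were a stricter threshold (−log10 p of at least 32), lists of equal length, the 1000 top peaks, factors with at least 500 peaks in both lists, families as units, other overlap and distance rules, other matching of random genes, and leaving out each factor in turn.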

Results

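The binding of 21 transcription factors to the Arabidopsis thaliana genome was measured by ChIP-seq in whole seedlings with and without abscisic acid (ABA), the plant hormone of drought and seed dormancy. Each factor carried the fluorescent protein YPet, added by recombineering (tagging inside a large cloned piece of the factor's own genomic region), and was precipitated with an antibody against GFP. Seedlings were grown for 3 days in the dark and then given 10 µM ABA or ethanol alone (mock) for 4 h. The series holds 122 libraries of tagged lines, with 3 libraries per treatment for 19 factors and 2 for ANAC102 and ZAT6, and 2 control libraries in which untagged Col-0 chromatin was precipitated with the same antibody. Both control libraries are labelled as treated with 10 µM ABA. The 21 factors belong to 10 families. They comprise the bZIP proteins ABF1, ABF3, ABF4, GBF2 and GBF3, the homeodomain-leucine zipper proteins HB5, HB6, HB7 and HAT22, the NAC proteins ANAC032, ANAC102 and RD26, the MYB proteins MYB3 and MYB44, the MYB-related protein encoded by AT5G04760, the NF-Y subunits NFYB2 and NFYC2, and DREB2A, HSFA6A, ZAT6 and FBH3. Each of the 42 peak lists pools the replicates of 1 factor and treatment, so no list has a replicate error of its own and the factor served as the unit of all tests across factors. The lists hold 15 to 18096 peaks on chromosomes 1 to 5 (TAIR10). Read depth is unknown, because the lists give no read counts.

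The first comparison asked whether a factor was found at more sites under ABA. For 19 of the 21 factors the ABA list was longer than the mock list, and the lists summed to 194733 peaks under ABA and 131965 under mock. The largest ratios were those of DREB2A, an AP2/ERF factor of dehydration and heat responses, with 1517 peaks under ABA and 15 under mock, and of the heat shock factor HSFA6A, with 1861 and 32. ANAC032 had 7977 and 801 peaks, HB7 had 13565 and 3645, and ABF1 had 8512 and 2494. The lists of GBF2 differed little, with 10724 and 10329 peaks. FBH3, a bHLH protein, went the other way with 194 peaks under ABA and 1084 under mock, and HB5 had 9558 and 10026. The mean log2 ratio of ABA to mock peaks was 1.13 ± 2.01 (SD, n = 21 factors), and its median was 0.54 (two-sided sign-flip permutation test of the mean, p = 0.00704). With the mean of each of the 10 families as the unit the mean log2 ratio was 1.54 and did not pass the test (exact sign-flip permutation test, p = 0.111). Among the 18 factors with at least 500 peaks in both lists the mean was 0.76 (permutation test, p = 3e-05). That limit leaves out DREB2A and HSFA6A, and also FBH3, the factor with the large fall. Leaving out FBH3 alone gave a mean of 1.31 (permutation test, p = 2e-05), so the smaller p is not firmer evidence from longer lists.

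**Figure D1:**
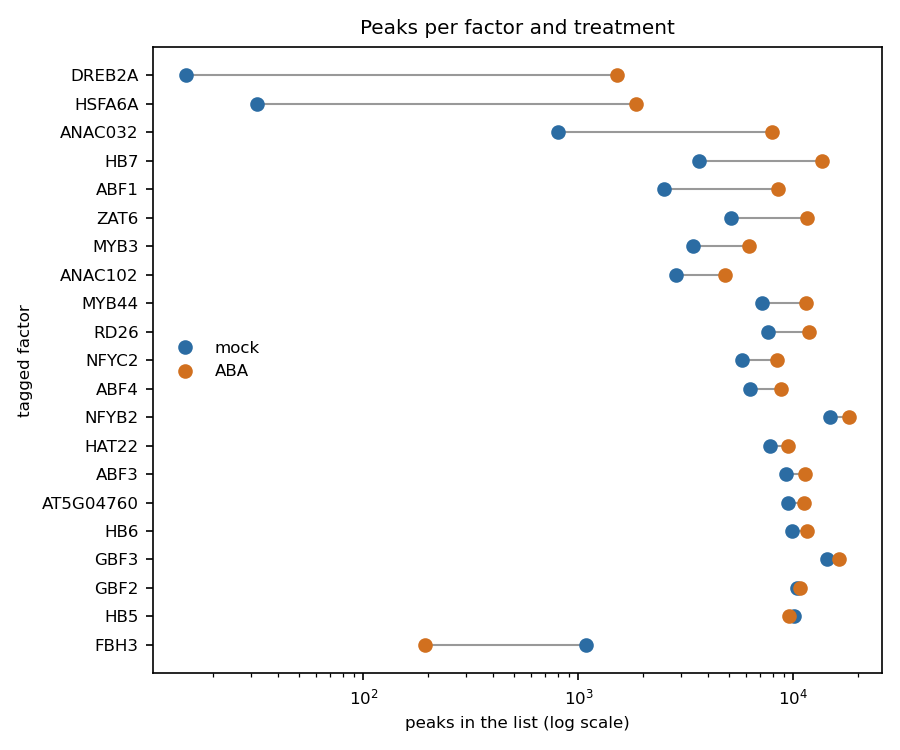
Number of peaks (x axis, log scale) in the pooled list of each tagged factor (y axis) under mock (blue) and ABA (orange), ordered by the log2 ratio. DREB2A (1517 against 15) and HSFA6A (1861 against 32) stand farthest apart, and FBH3 (194 against 1084) and HB5 (9558 against 10026) have the longer list under mock.

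The second comparison asked how far the sites under ABA overlapped those under mock. Nearly all mock peaks overlapped an ABA peak of the same factor, by at least 1 bp, for most factors. The share was 99.4% for ABF1 (95% Wilson interval 99.0 to 99.6%), 99.3% for HB7 (99.0 to 99.5%) and 98.8% for MYB44 (98.5 to 99.0%), and lowest, among factors with a longer ABA list, at 88.2% for RD26 (87.4 to 88.9%). The reverse share was 28.8% of ABA peaks for ABF1 (27.8 to 29.8%), 25.5% for HB7 (24.8 to 26.2%), 9.89% for ANAC032 (9.25 to 10.6%) and 89.2% for GBF2 (88.6 to 89.8%). FBH3 was the exception, with 14.9% of its mock peaks found under ABA (12.9 to 17.2%) and 83.0% of its ABA peaks found under mock (77.1 to 87.6%). Over the 21 factors, 92.1% ± 18.0 (SD) of mock peaks overlapped an ABA peak and 57.5% ± 29.0 of ABA peaks overlapped a mock peak, a mean difference of 34.6 percentage points (sign-flip permutation test, p = 0.00064). Both shares count nearly the same overlaps over the length of each list, so the difference was positive for the 19 factors with the longer ABA list and negative for FBH3 and HB5, and its test repeats that of the peak number. It does not decide between added and replaced sites. Much of the overlap was also not specific to the factor. The mock peaks of ABF1 overlapped the ABA list of another factor at a median of 85.7% (up to 98.9% for NFYB2), those of HB7 at 82.0% (up to 99.7% for HB6), and the median over the 21 factors was 74.4%. When both lists of a factor were cut to the length of the shorter one by the caller's −log10 p, the difference was 2.21 points (permutation test, p = 0.00054). Lists of 1 length can differ here only where a peak meets several, so this does not test whether sites were kept. After the cut 76.6% ± 16 (SD, n = 21) of the ABA peaks were shared. Under that cut the share was 92.7% for GBF3, 90.9% for NFYB2, 54.7% for ANAC032 and 39.7% for FBH3. In the lists of all 21 factors the peaks shared with mock had a higher median −log10 p (the authors' value per peak) than those found under ABA alone.

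Sites found under ABA alone lay near genes about as often as shared sites. Of the summits of ABA peaks, 33.6% ± 3.76 (SD, n = 21) lay inside a protein-coding gene, 50.4% ± 4.13 lay outside genes within 1000 bp of the nearest one, and 6.67% ± 0.683 lay more than 2000 bp from any. The share near genes was 51.4% in peaks found under ABA alone and 49.5% in shared peaks, a mean difference of 1.96 points (sign-flip permutation test over 20 factors, p = 0.191). The difference was positive for 16 of the 20 factors, among them ANAC032 (5.82 points) and HB5 (5.21 points). GBF3 stood far below the others at −16.9 points, and FBH3 far above at 18.0 points with 33 peaks found under ABA alone. Without GBF3 the mean was 2.96 points and passed the test (permutation test, p = 0.00142), with lists of equal length it was 2.99 points (p = 0.0486), and with a reciprocal overlap of 50% it was 0.165 points (p = 0.878).

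The 3 pairs of factors with the highest overlap each came from 1 family. ABF1 and ABF4, bZIP proteins that bind ABA-responsive promoters, had a Jaccard index (shared regions over all regions of either list) of 0.743 under ABA, HB6 and HB5 had 0.740, and ABF4 and ABF3 had 0.725. RD26 and ZAT6, of different families, came next with 0.706. The log2 ratio of shared regions to those expected from the list lengths was 0.96 ± 0.27 (SD) over the 21 pairs within families and 0.89 ± 0.37 over the 189 pairs between families, and the difference of 0.08 did not pass a permutation test of the family labels (p = 0.424). The setting decided this call. With the 1000 top peaks of each list, which leaves out FBH3 for its 194 peaks, the difference was 1.22 (permutation test, p = 1e-05, the smallest that 100000 permutations can give), with peaks of −log10 p of at least 32 it was 0.28 (p = 0.00148), among the 18 factors with longer lists 0.20 (p = 0.00039), and without FBH3 0.14 (p = 0.0416).

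The lists of different factors overlapped more under ABA. The mean Jaccard index over the 210 pairs was 0.391 under ABA and 0.265 under mock, and 184 pairs had the higher index under ABA (permutation test swapping the treatments within factors, p = 0.00253). The pair ANAC032 and RD26 went from 0.115 to 0.586, and ANAC032 and ABF3 from 0.0817 to 0.536. HB6 and HB5 had 0.769 under mock and 0.740 under ABA, and the pair FBH3 and MYB3 had 0.236 under mock and 0.0343 under ABA. FBH3 had higher values under ABA with HSFA6A (0.0643 against 0.0105) and DREB2A (0.0529 against 0.00384), whose mock lists are the shortest. In lists cut to equal length the mean difference was 0.0125 in place of 0.127 (permutation test, p = 0.00148). All lists together covered 21939 separate regions. Of these, 4469 were bound by at least 15 factors under ABA and 1565 under mock, where independent placement of lists of these lengths gives 6.92 and 0.00946, and 61 regions were bound by all 21 factors under ABA. Some of the 61 are long merged stretches that hold the wide peaks over a tagged factor's own gene, described below. Examples are 59718 bp at DREB2A and 59997 bp at NFYB2, where the factors need not share a site.

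Each summit was given to the nearest protein-coding gene within 2000 bp, and the number of factors was counted for each of 27432 genes. Genes bound by at least 10 factors numbered 7240 under ABA and 4231 under mock (permutation test swapping the treatments within factors, p = 1e-05, the smallest possible). In lists cut to equal length the difference was 175 genes in place of 3009 (permutation test, p = 0.0218). At least 1 factor was placed at 19428 genes under ABA and at 17384 under mock. All 21 factors were placed at 27 genes under ABA. The first 5 of them in the fixed order had 19 factors under mock and included TPL, which encodes the co-repressor TOPLESS, RCD1, a protein of stress signalling, Cand1 (AT1G57680), AT1G09520 and AT1G68670.

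The 10 genes with the largest net gain had between 14 and 19 factors under ABA. AT2G39355 had 18 factors under ABA and 2 under mock, AT1G17310 had 17 and 3, PMSR1, a methionine sulfoxide reductase, had 16 and 2, and AT5G53710 had 14 and 0. UCP5, a mitochondrial carrier, had 19 and 6, and the methylesterase family member MES5 had 18 and 5. AT1G21470 had 17 and 4, while AIR3, AT4G35690 and the squalene epoxidase-like gene SQP2 each had 16 and 3. At the other end, the kinase gene MPK15 had 10 factors under ABA and 18 under mock, GTE7 had 12 and 19, and DWF1, an enzyme of brassinosteroid synthesis, had 1 and 8. AT2G41945 had 10 and 16, AT1G80440 had 9 and 15, the transporter gene OPT6 had 8 and 14, and AT1G76185 had 5 and 11. AT3G63210 had 14 and 19, and AT4G37550 and AT5G65650 each had 8 and 13. A peak counts for 1 gene through its summit, so a moved summit or merged peak can change these numbers without lost binding. For HB7, 25 mock peaks overlapped no ABA peak, while 169 genes lost the factor. The region whose middle lies nearest to AT3G63210 was touched by 19 factors in both treatments. The same limit holds for the single genes named below. None of the 19780 genes with any factor passed an exact sign test of factors gained against factors lost after Benjamini-Hochberg adjustment (lowest adjusted p = 0.186), while 2218 genes with more gains and 4 with more losses had an unadjusted p below 0.05. These counts follow the longer ABA lists, since 86.7% of all changes were gains. Against that share, a setting chosen after the data were seen, 912 genes with fewer gains had an unadjusted p below 0.05 and 20 passed after adjustment. With 21 factors no gene can pass this setting for more gains, so it tests fewer gains alone.

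The gene at the ABA peak with the highest −log10 p was taken for each factor. For both ABF3 and ZAT6 it lay outside the gene next to MAPKKK18, an ABA-induced protein kinase gene, on chromosome 1 from 1467377 to 1470040 for ABF3, 269 bp from the gene, and from 1467347 to 1471468 for ZAT6, 276 bp from it. For ZAT6 no mock peak overlapped it. For ANAC032 it lay next to DIS2 (chromosome 1, 10958150 to 10961184), a gene of the actin-nucleating ARP2/3 complex, and for ANAC102, where it was tied with 1 other peak, also next to DIS2 (10957388 to 10960655). ABF1 had its strongest peak next to AFP3, of a family of proteins that bind the regulator ABI5 (chromosome 3, 11382640 to 11388065, 2 peaks tied). HAT22 and the AT5G04760 factor had theirs inside MEE14 on chromosome 2 (6921801 to 6922518 and 6921550 to 6922781). DREB2A had its strongest peak next to the auxin repressor gene IAA9 (chromosome 5, 26252502 to 26254318) and HSFA6A inside the chaperone gene CLPB4 (chromosome 2, 10701647 to 10702487). MYB3 was strongest next to the chaperonin gene CPN20, NFYC2 next to the polyamine oxidase gene PAO3, HB5 next to AIF1 and GBF2 next to AT3G14160. HB6, HB7 and ABF4 were strongest next to AT1G27030, AT5G36925 and AT5G48610, and RD26 and MYB44 inside AT4G00695 and AT3G05990. For GBF3, 40 peaks shared the top value, the first of them inside CYP86A4, and for NFYB2 3 peaks did, the first inside PSB27. The peaks of NFYB2 and of ANAC102 over their own genes (36698 and 50464 bp wide) were among their tied top peaks. The strongest peak of FBH3, with its summit inside the histone gene HTA10, was 31856 bp wide and also overlapped the gene of FBH3 itself.

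Among 22 factor and target pairs fixed from the literature, 12 had a peak placed at the target under ABA and 9 under mock, with 8 in both. Over all factors and genes, 26.7% of pairs were present under ABA and 18.4% under mock. Dehydration and ABA response genes, which include several of the targets, had a mean of 12.8 of the 21 factors under ABA. A peak at a target is therefore not by itself specific to the pair. RD29B, a dehydration gene with ABA-responsive elements, had a peak of ABF3 (chromosome 5, 21236550 to 21241230, 83 bp from the gene) and of ABF4 (21236589 to 21237504, 53 bp) in both treatments and of ABF1 under ABA alone (21236609 to 21238632, inside the gene). DREB2A had peaks at RD29A (chromosome 5, 21236676 to 21244645) and at HSFA3 (973539 to 974788), both inside the gene and both in the ABA list alone. GBF3 and GBF2 had peaks at ADH1 (chromosome 1, 28974841 to 28975547 and 28974880 to 28975552), MYB3 inside C4H (chromosome 2, 12995626 to 12996303), MYB44 at PP2CA (chromosome 3, 3584452 to 3588527) and HSFA6A at HSP70 (chromosome 3, 3993506 to 3994192) in both treatments. At ERD1, RD26 had a peak in both treatments and ANAC032 under ABA alone. The 4 pairs found under ABA alone are those of DREB2A, ANAC032 and ABF1. The mock lists of these factors hold 15, 801 and 2494 peaks, so absence under mock can follow from the short lists. HB6 had a peak at ABI1 under mock alone. The other 9 pairs had none, and they include ABF3 and ABF4 at RAB18, HB5, HB7 and MYB44 at ABI1, HB7 at ABI2, NFYB2 and NFYC2 at FT, and FBH3 at CO.

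The gene lists addressed which pathways were bound by more factors than random genes with a similar distance to their neighbours. Genes of dehydration and ABA response, such as the RD29, LEA and COR genes, had a mean of 12.8 factors under ABA (n = 32 genes), against 5.68 in random lists (95% of lists 3.72 to 7.78, permutation test with 10000 random lists, adjusted p = 0.00055). The CBF and DREB regulators of cold and drought had 16.5 factors against 7 (n = 8 genes, permutation test, adjusted p = 0.00055), with CBF1 at 20 factors, CBF2 and CBF3 at 19 and ICE1 at 17. The clade A PP2C phosphatases, which switch off ABA signalling, had 14.0 against 6.37 (n = 9, permutation test, adjusted p = 0.00088), with HAB1 at 18, PP2CA, AHG1 and HAI2 at 17, and ABI1 at 4. The SnRK2 kinases, which pass the ABA signal on, had 11.1 against 5.59 (permutation test, adjusted p = 0.0106), with SNRK2.3 at 19, SNRK2.1 and SNRK2.5 at 16 and SNRK2.10 at 15. Genes of ABA synthesis, breakdown and transport had 11.5 against 6.19 (permutation test, adjusted p = 0.00102), with the synthesis gene NCED3 at 20, the breakdown gene CYP707A2 and the transporter gene NPF4.6 at 19, and ABA1 and CYP707A1 at 18. The PYR/PYL receptors of ABA had 8.57 against 6.55 and did not pass the test (n = 14, permutation test, adjusted p = 0.243), with PYL5 at 21, PYL4 and PYL8 at 16 and PYR1 at 14.

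Lists of other pathways also stood above random genes. The circadian clock list had 14.8 factors per gene against 5.29, with GI at 20, PRR5 at 19, and PRR7 and ELF4 at 18, the Aux/IAA auxin repressors had 15 against 6.57, with IAA2 at 20, IAA3 at 18, and IAA4, IAA7 and IAA19 at 17, and the 21 factors' own genes had 14.3 against 6.11. Brassinosteroid genes had 14.4 against 6.54, with BIN2 and DWF4 at 19, light signalling genes 14.3 against 6.22, with PIF3 and PIF4 at 19, and gibberellin genes 13.8 against 6.86, with RGA at 20 and GID1B, GA2OX6 and GAI at 19. Jasmonate genes had 13.6 against 6.49, cytokinin genes 12.8 against 6.61, and ethylene genes 12.7 against 6.53, with JAZ1, ARR9 and EIN2 among the members at 18 factors. The phenylpropanoid and flavonoid list had 10.1 against 6.25, with C4H at 18, and the list of constitutive reference genes, fixed as a group unrelated to ABA, had 10.2 against 5.98, with ACT7 at 21 and UBQ10 at 20. In total 16 of the 22 lists had more factors than random genes in the permutation test, with adjusted p between 0.00055 and 0.044, and 15 of these 16 also did so under mock. Genes of seed storage and embryo development had fewer, with 1.43 against 6.19 (n = 14, permutation test, adjusted p = 0.00189), and 6 of the 14 members had no factor in either treatment. Heat shock genes (7.53 against 4.69), guard cell channels, pumps and oxidases (9.89 against 6.46), light-harvesting genes (8.38 against 5.77) and floral organ identity genes (10.4 against 6.77) did not pass the test.

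Dehydration and ABA response genes were the 1 list of the 22 that gained more factors under ABA than random genes. The mean rose from 8.25 factors under mock to 12.8 under ABA, a net gain of 4.50 per gene against 1.77 in random lists (95% of lists 1 to 2.62, permutation test, adjusted p = 0.0044). Of its 32 members, 25 had more factors under ABA, 5 had fewer and 2 the same number, and 15 had a net gain of at least 5. MAPKKK18 had 20 factors under ABA and 9 under mock, the dehydrin gene LTI30 had 13 and 2, and the late embryogenesis abundant gene LEA4-5 had 17 and 7. RD22 had 14 and 5, LEA7 had 13 and 4, and the lipid transfer protein gene LTP4 had 10 and 1. RD29B had 15 and 7, RD20 had 16 and 8, GOLS2, an enzyme of raffinose sugar synthesis, had 20 and 12, and EM6 had 11 and 3. RD29A had 14 and 7, ADH1 had 16 and 9, LTP3 had 13 and 7, RAB18 had 7 and 1, and ERD1 had 14 and 9. Of the members with a net gain below 5, LEA14 had the most factors, with 20 and 16, followed by HVA22D with 19 and 15 and AFP1 with 19 and 17. The members with fewer factors under ABA were AFP2 (7 and 10), AFP3 (14 and 17), COR47 (15 and 16), ERD10 (12 and 13) and XERO1 (4 and 5). Of the factors, GBF3 was placed at 30 of the 32 genes under ABA and 29 under mock, and ABF3 and ABF4 each at 28 and 26. ANAC032 was placed at 21 and 2, ZAT6 at 23 and 8, HB7 at 21 and 6, and DREB2A at 11 and 0. Over all genes ANAC032 was placed at 6546 and 724, ZAT6 at 8991 and 4033, HB7 at 10525 and 3095, and DREB2A at 1363 and 15. Their rise is therefore not by itself particular to this list. MYB3 had 10 and 1 of the 32 genes, against 5066 and 2831 over all genes. HAT22 had 18 and 8, against 7309 and 5951. In lists cut to equal length the net gain was 1.62 per gene against 0.0698 in random lists (permutation test, adjusted p = 0.0044), and against random genes with the same number of factors under mock it was 4.50 against 2.68 (adjusted p = 0.0044).

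**Figure D2:**
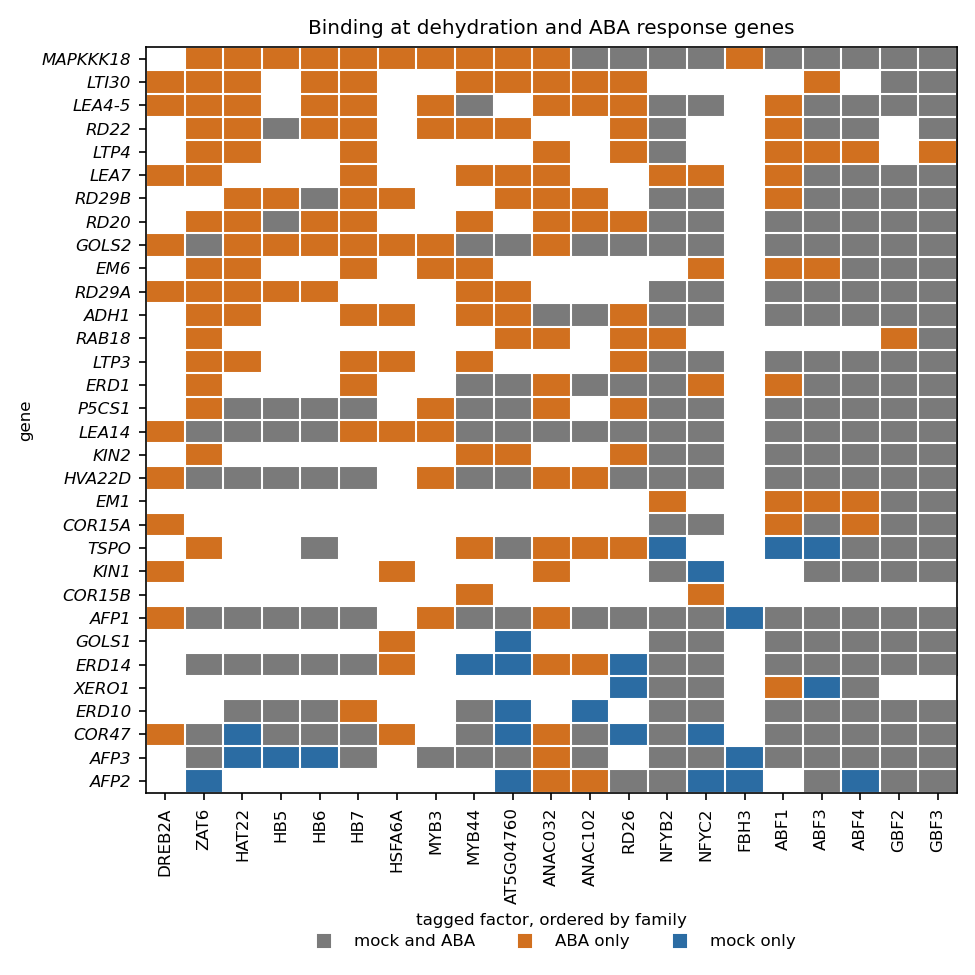
Placement of each tagged factor (x axis, ordered by family) at each of the 32 dehydration and ABA response genes (y axis, ordered by net change). Grey marks a peak in both treatments, orange under ABA alone and blue under mock alone. The bZIP columns are mostly grey, and the upper rows, such as MAPKKK18 and LTI30 with 11 factors gained each, are mostly orange.

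The other 21 lists did not pass the test of the net gain, although 4 of them had an unadjusted p below 0.05. Genes of ABA synthesis, breakdown and transport had a net gain of 3.37 against 1.80 (permutation test, adjusted p = 0.0939), with ABA4 at 14 factors under ABA and 5 under mock, CYP707A3 at 15 and 9, and ABCG25 at 16 and 11. The CBF and DREB list had 4.12 against 2.09 (permutation test, adjusted p = 0.206), with ZAT10 at 12 and 3 and DREB2B at 16 and 8. The phenylpropanoid and flavonoid list had 3.38 against 1.88 (permutation test, adjusted p = 0.206), with CHS at 11 and 3, CHI and LDOX at 9 and 3, and DFR at 7 and 2. Seed storage and embryo genes had 0.286 against 1.87 (permutation test, adjusted p = 0.0858). Lists of ABA signalling gave 3.00 against 1.91 for the PP2C phosphatases, with HAB1 at 18 and 8 and HAI3 at 14 and 6, 3.10 against 1.77 for the SnRK2 kinases, with SNRK2.9 at 8 and 1, and 1.07 against 1.95 for the PYR/PYL receptors, with PYL4 at 16 and 17 and PYL6 at 12 and 14. Single members with large values in other lists were GORK (11 and 2), LOX3 (15 and 6), CPD (17 and 9), HY5 (15 and 7), COP1 (15 and 8), ARR16 (10 and 2), MBF1C (18 and 11) and AP1 (17 and 9). Net gains of 5 or 6 factors were found at SNRK2.4 (7 and 2), NCED5 and AAO3 (8 and 3), DREB2C and GA20OX2 (14 and 9), RBOHF (20 and 15), ERS2 (18 and 13), ACS6 (17 and 12), JAZ12 (18 and 12), JAZ11 (10 and 4), GA3OX1 (17 and 11), BZR1 and GAPC1 (15 and 9), BAK1 (15 and 10), ARR8 (19 and 14), HSP17.4 (5 and 0), PAL1 (11 and 6), PP2AA3 (9 and 4), NPF4.6 and HB7 (19 and 14), ICE1 (17 and 12) and ABF1 (16 and 10), besides those named above. With peaks of −log10 p of at least 32 alone, 9 lists passed the test, the dehydration list among them, and with every gene in a window of 1000 bp around a summit 2 lists did.

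**Figure D3:**
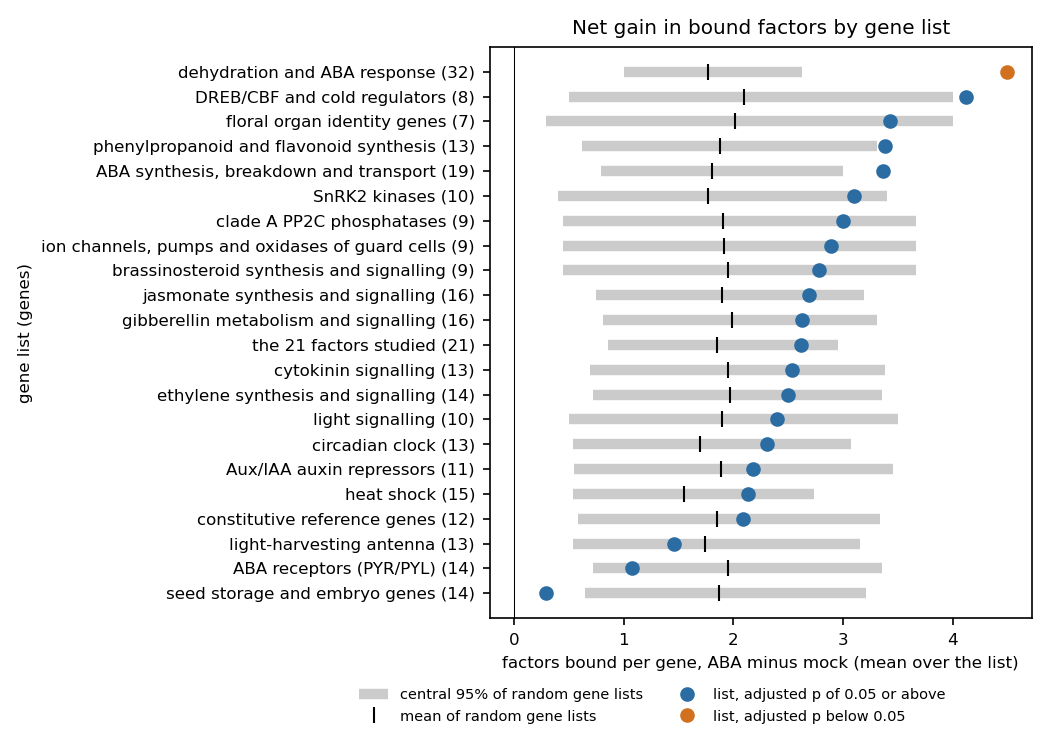
Mean net gain in bound factors per gene, ABA minus mock (x axis), for each of the 22 gene lists (y axis, number of genes in brackets), with the mean (black tick) and the central 95% (grey bar) of 10000 random gene lists. The dehydration and ABA response list, at 4.50, is the 1 list past the adjusted threshold (orange).

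The genes of the 21 factors were themselves bound by many of the factors. Of the 441 possible links from a factor to the gene of a factor, 301 were present under ABA and 246 under mock, which is 68.3% and 55.8%, against 26.7% and 18.4% over all genes. FBH3 had 21 factors at its gene under ABA and 18 under mock, NFYB2 had 20 and 18, HSFA6A had 19 and 10, ZAT6 had 16 and 9, and ABF4 had 13 and 7. GBF3 had 2 in both treatments and NFYC2 none. ANAC032 was placed at 18 of the 21 genes under ABA and 3 under mock, HSFA6A at 11 and 0, and FBH3 at 3 and 6. The mean change was 2.62 ± 4.09 links per factor (SD, n = 21), with 15 factors higher and 2 lower (sign-flip permutation test, p = 0.00279). Per gene of the 21 the gain was 2.62 factors against 1.85 in random genes, which did not pass the test (permutation test, adjusted p = 0.475), so the rise was not shown to exceed that of genes at large. In lists cut to equal length it was 0.238 and did not pass the test (permutation test, p = 0.621).

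Every one of the 21 factors had a peak over its own gene in both treatments, and these peaks were wide. Their median width was 28124.5 bp, against 956 bp over all peaks, and they lay over a median of 7 genes. With the wider of the 2 peaks of each factor, the widest were those of HAT22 under mock (66292 bp, chromosome 4), ANAC032 under ABA (63695 bp, chromosome 1) and NFYB2 under mock (59888 bp, chromosome 5). In the lists of the other 20 factors, the widest peak at the same genes was 11922 bp. Because one summit stands for each peak, 12 of the 21 factors were placed at their own gene under ABA by the nearest gene rule, where random pairing of factors and genes gives 14.3 (permutation test, p = 0.244). By any base of a peak on the gene, a setting chosen after the data were seen, 21 of 21 were, where random pairing gives 17.9 (permutation test, p = 0.00866). That all 21 would be was already known from the peaks named above. In the flanks from 10 to 40 kb on each side of the own gene, 20 of 21 factors had a summit, where random pairing gives 19.5 (permutation test, p = 1.0).

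**Figure D4:**
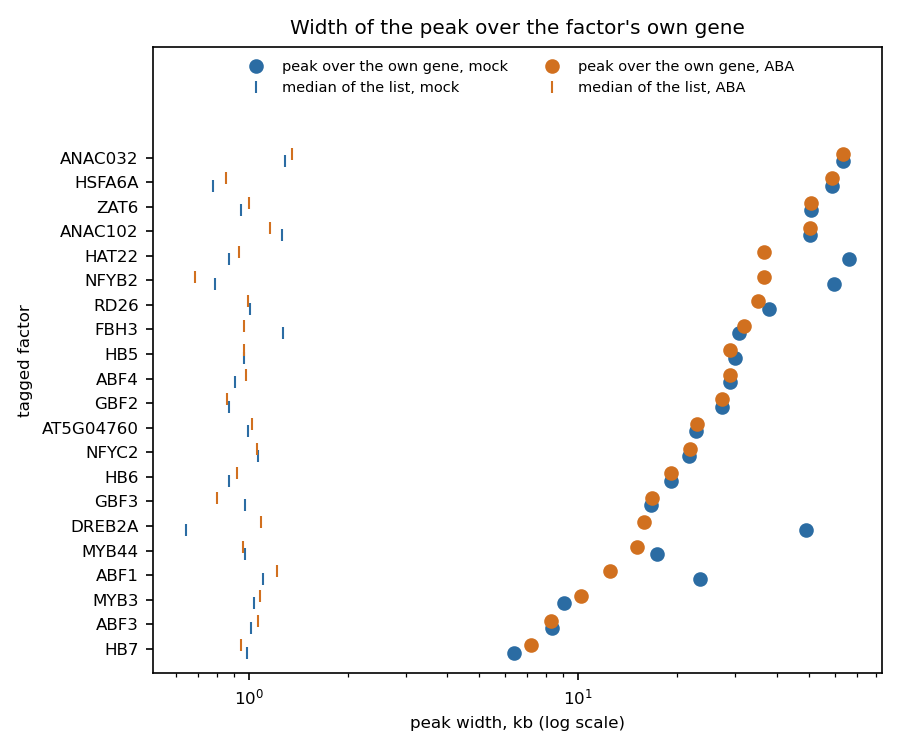
Width in kb (x axis, log scale) of the widest peak over the gene of each tagged factor (y axis) under mock (blue) and ABA (orange), with the median width of all peaks of the same list as a tick. The peaks over the own gene measure from 6395 bp (HB7, mock) to 66292 bp (HAT22, mock).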

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

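The test of the widest peaks at the own genes, the use of the planned lists of equal length to test depth at the dehydration genes and the test over other splits of the lists were chosen only after the result was seen.

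FBH3 and HB5 differed from the other 19 factors in having fewer peaks under ABA than under mock, with log2 ratios of −2.48 for FBH3 and −0.069 for HB5. The difference between these factors and the rest was not tested, since each has 1 pooled list per treatment. Of the 922 mock peaks that FBH3 lacked under ABA no cause can be named from the lists.

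The lists of the other factors were longer under ABA, which a lower depth or yield of the mock libraries could give. Such a loss thins a list from its weak end, and in the 17 factors with at least 2000 peaks in both lists a mean of 0.988% of the 500 top ABA peaks was absent from the mock list (95% bootstrap interval 0.329 to 1.76%), from 0 to 5.4% by factor. So this explanation stays open for the general gain in peaks. A loss from the weak end alone is argued against for the dehydration and ABA response genes. There the net gain was 1.62 factors per gene in lists of equal length, above the 95% range of random lists (−0.469 to 0.625). A lower yield that also disturbs the order of the mock peaks is not removed by this cut and stays open there too. ANAC032, whose mock list holds 801 peaks, lacked 34.8% of its 500 top ABA peaks under mock. For DREB2A and HSFA6A the share says nothing, as their mock lists hold 15 and 32 peaks. A larger amount or stronger binding of the factors under ABA, which the treatment could bring, was not tested.

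NFYC2 had a second stretch of wide peaks, on chromosome 5, away from its own gene on chromosome 1, in data that no comparison was about. It ran over 74.9 kb and 16 genes, and its widest peak measured 45965 bp under mock (3491342 to 3537306) and 42554 bp under ABA (3500375 to 3542928). The widest peak of any other factor's list there measured 8305 bp.

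Wide peaks over the factor's own gene may come from extra copies of the region carried by the tagged transgene, since recombineered constructs hold long genomic inserts. In 15 of the 21 factors the widest peak of the list covered the own gene in both treatments, and the peaks over own genes lay over a median of 7 genes. These wide peaks had been seen before the test was chosen, so it restates them and does not decide for extra copies. Of the 42 lists, 37 had a peak over 10 kb at the own gene, against 1 of 840 comparisons with lists of other factors at these genes. So the width went with the line in which that gene was tagged. This contrast cannot separate extra copies from binding of a factor to its own gene, since both would show in the factor's own lists alone. Extra copies, the tag's own effect and binding to the own gene stay open. For the second stretch of NFYC2 no explanation was tested.

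The real assignment of treatments gave 2222 genes with a changed number of factors at an unadjusted p below 0.05 in the exact sign test, and the highest of the other splits, which swap the treatments within factors, gave 658, so 1 of 100 splits, the real one, was as large. With the 21 factors as separate units, this argues against chance for the count and does not exclude it. The count restates the change in peak number, which with families as units did not pass its test (1.54 on the log2 scale, exact sign-flip permutation test, p = 0.111), and it singles out no gene.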

How the results depend on the processing

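Settings with FBH3, or FBH3 and HB5, left out on purpose, with the own region left out, with any base of a peak on the own gene, with equal lists of the longer lists alone, and with gains as likely as over all genes were chosen after seeing the data. Of 274 alternative values of 11 results, 261 kept their direction and their side of the threshold (counts without a p within 1.5 times). Among them were 208 of the 210 that leave out 1 factor and 53 of the other 64. A value can keep its side at a much smaller size. With family means as units the peak count change was 1.54 on the log2 scale and no longer past the threshold (exact sign-flip permutation test, p = 0.111), a test with 10 units in place of 21. In lists of equal length the links among the factors changed by 0.238 per factor (p = 0.621 in the permutation test), and the difference in the share near genes was 2.99 points and past the threshold (p = 0.0486). The kept share difference (2.21 points), the co-binding change (0.0125) and the number of multi-factor genes (175 in place of 3009) stayed past it at much smaller size. For the kept share the construction shows why, since lists of 1 length differ in overlap only where a peak meets several. Within-family similarity was past the threshold at the strict −log10 p (0.28), with the top peaks of each list, which leaves out FBH3 (1.22), and with longer lists alone (0.20). The ratio used has a lower ceiling for longer lists, and how far this accounts for the change was not tested. The count of gene lists with more factors gained was 9 at the strict −log10 p and 2 with every gene in a window, and the dehydration list passed in all 30 settings, the planned one included. Binding at the own gene turned from below to above the random expectation in its flanks (20 factors) and by any base (21 factors). Genes with a changed number of factors numbered 20 once gains were taken as likely as over all genes (86.7%), where with 21 factors only fewer gains can pass, and 0 otherwise (exact sign test, 2222 at an unadjusted p below 0.05).

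Leaving out each factor in turn (leave-one-out) gave a difference in the share near genes from 1.12 to 2.96 points, past the threshold without GBF3, and a within-family similarity from 0.047 to 0.14, past it without FBH3. The other ranges were 0.85 to 1.31 for the peak count change, 31.4 to 39.8 points for the kept share difference, 0.104 to 0.151 for the co-binding change, 2628 to 3137 for multi-factor genes, 2 to 2.9 for the links, 11 to 12 for the own gene, 15 to 17 for lists bound by more factors and 1 to 1 for lists with more gained. No paired analysis was possible because each group has 1 list that pools its replicates, which rules out pairs of replicates, while the tests across factors pair the treatments of each factor. The planned motif results were not run, as no genome was used here. Organelle peaks could not be included, because the lists hold chromosomes 1 to 5 alone. Depth is unknown, so the length of a list and what it misses cannot be separated from library depth or yield.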

Other observations

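The receptor genes were picked from the planned lists of equal length, and their test chosen, only after the result was seen, unlike the test of shared regions. Factors of different families shared many regions. Those bound by all 21 factors under ABA included the one at CBF1 (chromosome 4, 13020494 to 13025201, 19 factors under mock), 1 whose middle lies nearest to the actin gene ACT7 (chromosome 5, 3048779 to 3052825, 19 under mock) and 1 nearest to the phosphatase gene HAI1 (chromosome 5, 23893409 to 23901632, 17 under mock). The median width of the 4469 regions of at least 15 factors was 2783 bp, against 879 bp for the others, and they held 45.8% of the bases of all regions. GBF3 and NFYB2 had the largest shares of peaks in regions bound by no other factor under ABA, 13.4% and 6.13%.

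Regions bound by most factors could reflect background shared by all libraries and their common control, if all lists had the same one. The shortest lists should then consist of such regions, and 5 of the 5 shortest lists had a share of peaks in them above the median of all lists, which was 62.9%. The shares were 66.7% for DREB2A under mock, 65.6% for HSFA6A under mock, 95.9% for FBH3 under ABA, 75.5% for ANAC032 under mock and 88.7% for FBH3 under mock. This does not decide, because the share fell with the length of a list in the other 37 lists too (Spearman correlation −0.959), a check added after the result was seen. Background of this kind and open chromatin that many factors reach both stay open.

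The PYR/PYL receptor genes had the lowest net change of all lists in lists of equal length, −1.29 factors per gene against 0.0405 in random lists, which did not pass the adjusted test (permutation test, p = 0.0054, adjusted p = 0.0594). The Aux/IAA and gibberellin lists came close, at −1.09 and −1.06 (permutation test, adjusted p = 0.185 and 0.0968), so a low value was not particular to the receptors.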
